A study of Mus musculus with 16 samples.

How the data were processed

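Total RNA from whole descending thoracic aorta of C57BL/6J and 129S6/SvEvTac mice, control or with AngII-induced hypertension, was sequenced in 16 libraries, 4 per group. Per the labels' protocols, tissue was crushed in lysis buffer, RNA was purified with a column kit and DNase, reads were aligned to GRCm38 (mm10) with HISAT2, and transcripts were quantified with StringTie against Gencode. The deposited values are expected counts per gene, already whole numbers, for 52636 genes. Per the submitters' processing notes, DESeq2 1.26.0 and R 3.6.2 were used, with no role stated. The Gencode release, the way counts were derived from StringTie and the strandedness are not given in the sources used here, so genes that overlap, run antisense or have near-identical copies are reported as uncertain.

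Gene names and positions were taken from GENCODE M21 on GRCm38, which matched 52403 genes to a name, 49035 of them with the same ID version, and left 233 without one. Those 233 held 0.033 to 0.0431% of each library's counts. Totals ran from 42116120 to 121573945 counts per library. No 2 replicates were identical, and the lowest chi-square per degree of freedom between replicates was 40.92. The labels do not state separate animals, so the p-values measure the spread between these samples, which may be technical.

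Counts were tested in R 4.3.3 with edgeR 4.0.16: filterByExpr with a minimum count of 10 left 17125 genes, TMM factors were computed, and a quasi-likelihood model with robust moderation and 1 mean per group was fitted over all 16 libraries. Benjamini-Hochberg adjusted p below 0.05 made a call. Standard errors were derived from the log2 fold change and the F statistic. The comparisons were AngII against control in each strain, the difference of those effects, and C57BL/6J against 129S6/SvEvTac in controls and with AngII. CPM are counts scaled to the TMM-adjusted library total, and log2 CPM used a prior count of 2.

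Before the files were seen, 29 gene lists were fixed from textbook knowledge. Together with the separate strain and sex label genes they held 671 entries, a gene in several lists counting in each, of which 3 had no match in the table and 27 lay below the filter. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, then with an estimated correlation and with fry. Fry tests a list's own genes without comparing them with other genes. Strain label genes (Nnt, Ren2, Casp4) and sex label genes were read singly; Ren2 has no entry in the table. Other measures per library were compared by exact permutation tests, whose smallest p with 4 against 4 is 0.0286.

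A rule fixed beforehand named genes: per comparison the 6 largest rises and 6 largest falls among called genes with a mean of at least 5 CPM in the higher group and no overlap between the samples of the groups, up to 3 called members per list by p, and a fixed panel. Unnamed gene models were left out, and some results are not reported. The genes described were picked from those the rule named with their behaviour under left-out libraries known, preferring ones whose call held; Casq2 lies outside the rule and was chosen after its value was seen. Of all called genes the rule named, calls held in every omission for 93 of 98 (AngII in C57BL/6J), 57 of 66 (AngII in 129S6/SvEvTac), 50 of 74 (difference of effects), 43 of 67 (strains, control) and 86 of 94 (strains, AngII). Folds against a group with no counts are lower bounds against 3 counts over the group.

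The pipeline was tested on counts simulated from each gene's mean over all 16 libraries and the real library sizes. Each gene was drawn independently, with 1 spread for all groups. In the C57BL/6J AngII group 200 genes were changed, far fewer than were called in the real data. The shares recovered hold for this setting only. For AngII in C57BL/6J, 94 of the 200 were called with 4 unchanged genes, recovering 22.4%, 40.3% and 78.8% at folds of 1.5, 2 and 4. For the difference of effects 62 were called with 7 unchanged genes (1.49%, 26.9% and 65.2%), and for the strains with AngII 96 with 4 unchanged genes (22.4%, 46.3% and 75.8%). Each step ran on 16935 genes. No gene was called in the other comparisons and 0 of 29 lists in any. As the simulated genes were independent, the list result cannot show how camera behaves where genes are correlated.

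Alternatives fixed beforehand were RLE scaling, library size only, no filter, a filter of 1 CPM in 4 samples, DESeq2 1.42.0, limma voom with sample weights, only the groups compared, a replicate block, adipocyte and muscle scores as covariates, and each library left out. Chosen after seeing the data were leaving out 2 libraries (C57BL/6J AngII 1, with the highest adipocyte score, 7.392, and 129S6/SvEvTac AngII 5, with the highest skeletal and cardiac muscle score, 2.568, both mean log2 CPM), protein-coding genes only, no switching genes, and no Gm42418, the largest gene in the table. Group labels were also reshuffled. A planned test of low counts was dropped as void and a label-switch test was dropped before being run.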

Results

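Gene expression was measured by RNA sequencing in 16 samples of whole mouse descending thoracic aorta, the part of the aorta that runs through the chest. The design crossed inbred strain (C57BL/6J or 129S6/SvEvTac) with treatment: control, or hypertension induced by angiotensin II (AngII), a peptide hormone that constricts vessels and raises blood pressure. Each of the 4 groups held 4 samples. Total counts per sample ran from 42116120 to 61381134 in 15 samples and reached 121573945 in 129S6/SvEvTac AngII replicate 5. Of the 52636 genes in the table, 17125 had enough counts to be tested. The labels do not state that the samples came from separate animals, so the p-values measure the spread between these samples. The AngII dose and duration are not given in the sources used here.

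The groups separated on the first 2 principal components, which held 36.1% and 21.4% of the variance. The 4 C57BL/6J AngII libraries stood apart on the first component, between -115.1 and -77.04, and replicate 3 lay nearest to its controls. Casp4, which encodes an inflammatory caspase and was fixed beforehand as a strain label gene, averaged 6.29 ± 1.44 CPM in C57BL/6J controls and 0.886 ± 0.596 CPM in 129S6/SvEvTac controls (SD, n = 4 each). Nnt, the other strain label gene measured, a mitochondrial transhydrogenase, did not separate the strains, at 4.57 ± 3.32 and 4.81 ± 5.46 CPM in the same groups. In the latter group replicate 2 stood at 13 CPM and the others at 1.95 to 2.17 CPM.

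**Figure D1:**
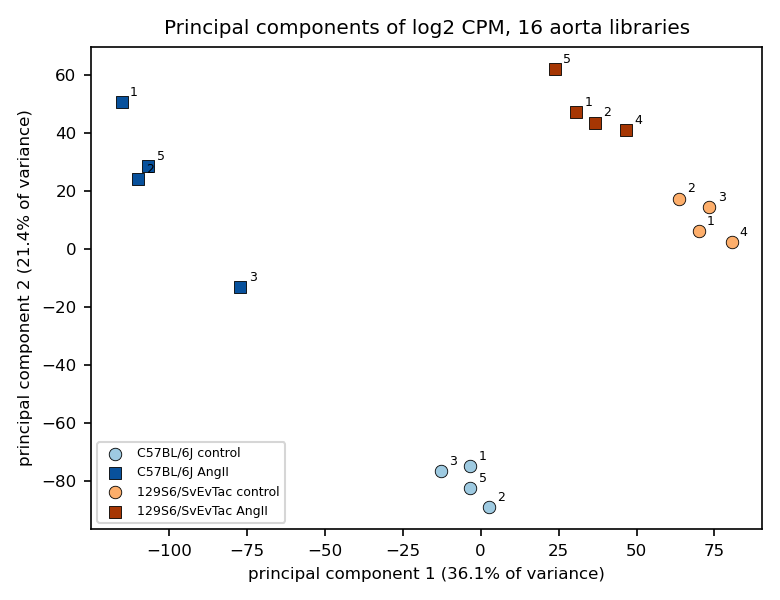
The first 2 principal components of log2 CPM over 16 aorta libraries, with the share of variance on each axis. Each point is 1 library with its replicate number, coloured by strain and treatment; the C57BL/6J AngII points lie between -115.1 and -77.04 on the first axis.

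The first comparison asked what AngII hypertension changed in C57BL/6J aortas. Of 20 collagen genes 18 rose, and of 26 smooth muscle contractile genes 23 fell and 1 rose, although the contractile list did not pass with an estimated correlation between genes (adjusted p = 0.132). The contractile list passed with fry (adjusted p = 2.23e-05). Col1a1, the main chain of type I collagen (ENSMUSG00000001506.10, GRCm38 chromosome 11, 94936224 to 94953042), went from 1926 ± 242 to 15164 ± 3185 CPM (SD, n = 4), a log2 fold change of 2.98 ± 0.26 (SE, adjusted p = 1.55e-06). Acta2, smooth muscle alpha-actin (ENSMUSG00000035783.8, chromosome 19, 34241090 to 34255590), went from 17958 ± 692 to 9294 ± 3140 CPM, a log2 fold change of -0.95 ± 0.18 (adjusted p = 0.000652). Myh11, smooth muscle myosin heavy chain (ENSMUSG00000018830.8, chromosome 16, 14194535 to 14291372), fell by 1.60 ± 0.26 on the log2 scale (adjusted p = 0.000235). Of 17125 genes, 3737 rose and 2927 fell by edgeR's quasi-likelihood test, 6664 in all.

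The collagen list had 18 of 20 genes higher (19 adjusted over the list alone) and none lower, with a median log2 fold change of 1.80 (camera adjusted p = 4.61e-26). Col5a2, a chain of type V collagen, rose 5.67-fold and Col8a1, a short-chain collagen, rose 38.9-fold. Among collagen processing and crosslinking genes 20 of 22 rose and 1 fell (20 and 1 adjusted over the list alone, camera adjusted p = 3.03e-15). Lox, the lysyl oxidase that crosslinks collagen and elastin, rose 7.47-fold and Plod2, a lysyl hydroxylase, rose 3.09-fold. Matricellular proteins and proteoglycans had 22 of 27 genes higher and 2 lower (23 and 2 adjusted over the list alone, median 1.54, camera adjusted p = 1.38e-13). Spp1, osteopontin, averaged 369 ± 353 CPM against 0.836 ± 0.499 CPM in controls. Postn, periostin, rose 3.20-fold. Matrix proteases and their inhibitors had 18 of 28 genes higher and 1 lower (19 and 1 adjusted over the list alone, camera adjusted p = 4.03e-12), with Adam12 up 145-fold, Timp1 up 18.1-fold and Mmp14 up 3.75-fold. These 4 lists also passed with an estimated correlation between genes, with adjusted p of 0.0155, 0.0374, 0.00864 and 0.00864 in the order given. Elastic fibre genes had 11 of 17 higher and 1 lower (11 and 1 adjusted over the list alone, camera adjusted p = 9.07e-05), among them Fbn1, which encodes fibrillin 1 and rose 3.04-fold. That call was lost with an estimated correlation (adjusted p = 0.131 with an estimated correlation). Eln, elastin, rose 3.48-fold.

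In the smooth muscle contractile list 23 of 26 genes fell and 1 rose (23 and 1 adjusted over the list alone), with a median log2 fold change of -1.07 (camera adjusted p = 2.1e-14; adjusted p = 0.132 with an estimated correlation). Ppp1r14a, an inhibitor of myosin phosphatase, fell by 1.65 ± 0.18 (SE) and Lmod1, leiomodin, by 1.47 ± 0.16 on the log2 scale. The gene that rose was Casq2, a calcium store protein of striated muscle, at 2.96 ± 1.08 (adjusted p = 0.0412); it was chosen for mention after its value was seen, and 1 library, C57BL/6J AngII replicate 1, stood at 7.96 CPM against 0.411 to 1.65 CPM in the others. Smooth muscle calcium and cGMP signalling genes had 12 of 25 lower and 1 higher (16 and 1 adjusted over the list alone, camera adjusted p = 0.000151; adjusted p = 0.355 with an estimated correlation). Gucy1a1, a subunit of the nitric oxide receptor, fell by 1.53 ± 0.26, while Ednra, the endothelin A receptor, rose by 2.23 ± 0.25.

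Most chemokine, macrophage and cell cycle genes rose in the same libraries. Ccl2, the monocyte-attracting chemokine (ENSMUSG00000035385.5, chromosome 11, 82035571 to 82037453), rose 22.6-fold, from 0.904 ± 0.507 to 20.4 ± 8.89 CPM (SD, n = 4). Il6, interleukin 6, had no counts in the controls and was at least 723-fold higher with AngII, and Tnn, tenascin N, at least 1260-fold higher, each against a floor of 3 counts over the 4 control libraries. Chemokines and cytokines had 23 of 28 genes higher and 1 lower (25 and 1 adjusted over the list alone, camera adjusted p = 2.8e-10; adjusted p = 0.0514 with an estimated correlation). Monocyte and macrophage markers had 23 of 28 higher (24 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.15e-13; adjusted p = 0.134 with an estimated correlation), with Cd68 up 5.71-fold, Adgre1 up 4.78-fold and Cd14 up 4.04-fold. Antigen presentation and dendritic cell genes had 15 of 20 higher (17 higher and 1 lower adjusted over the list alone, camera adjusted p = 3.05e-05; adjusted p = 0.349 with an estimated correlation), including H2-Eb1, a class II histocompatibility chain, up 6.57-fold. Interferon response genes had 22 of 27 higher (23 adjusted over the list alone, camera adjusted p = 0.000151; adjusted p = 0.514 with an estimated correlation). Their score stood at 4.262 and 4.012 mean log2 CPM in C57BL/6J AngII replicates 1 and 5 and at 2.788 and 2.756 in replicates 2 and 3, against 1.903 to 2.214 in the C57BL/6J controls. All 28 cell cycle genes rose (28 adjusted over the list alone), with a median log2 fold change of 4.56 (camera adjusted p = 4.61e-26; adjusted p = 0.0844 with an estimated correlation), Cenpe, a centromere motor protein, by 37.5-fold. Adipocyte markers also rose in these libraries, 24 of 26 with a median of 2.86 (25 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00015; adjusted p = 0.571 with an estimated correlation), while Plin4, a lipid droplet protein, fell 1.77-fold. The adipocyte score stood at 7.392 and 6.136 mean log2 CPM in C57BL/6J AngII replicates 1 and 5 and at 4.727 and 3.557 in replicates 2 and 3, against 4.252 in C57BL/6J control replicate 1 and 2.814 to 2.985 in the other controls of the strain. With the adipocyte score as a covariate the interferon call was lost (adjusted p = 0.0745), and the count of genes went to 4579.

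Endoplasmic reticulum stress genes had 15 of 23 higher and 1 lower (16 and 1 adjusted over the list alone, camera adjusted p = 2.9e-05; adjusted p = 0.349 with an estimated correlation), with Pdia4, a protein disulphide isomerase, up 2.03-fold. Adventitial fibroblast markers had 12 of 22 higher and 4 lower (13 and 4 adjusted over the list alone, camera adjusted p = 0.0028; adjusted p = 0.514 with an estimated correlation), with Lum, lumican, up 5.04-fold. Immediate early genes had 7 of 20 higher and 1 lower (9 and 1 adjusted over the list alone, camera adjusted p = 0.0248; adjusted p = 0.571 with an estimated correlation), with Socs3 up 7.69-fold and Myc up 8.55-fold; that call was lost without C57BL/6J AngII replicate 3 (adjusted p = 0.351) and without C57BL/6J control replicate 3 (adjusted p = 0.0557). Camera made no call for the remaining lists. These were T and NK cell (camera adjusted p = 0.0988), B and plasma cell (0.673), neutrophil and mast cell (0.0852), endothelial (0.232), skeletal and cardiac muscle (0.496), red blood cell (0.544) and nerve and Schwann cell (0.91) markers, and osteochondrogenic (0.0791), circadian clock (0.0626), oxidative phosphorylation (0.873) and renin-angiotensin and vasoactive (0.879) genes. TGF-beta and BMP signalling genes (0.601) and integrins, focal adhesion and mechanosensing genes (0.91) were not called either. In those last 2 lists, and in the skeletal and nerve lists, the median was above 0 while the test pointed down. Single genes in uncalled lists changed: Adra1d, an alpha-1 adrenergic receptor, fell 4.79-fold, Npr1, a natriuretic peptide receptor, fell 2.19-fold, and Smad6, an inhibitor of BMP signalling, fell 2.74-fold. The counts of Plod2, Plin4, Adra1d and Col3a1 are uncertain, because each shares exon positions with another gene. Agtr1a, which encodes an AngII type 1 receptor (ENSMUSG00000049115.15, chromosome 13, 30336441 to 30382867), had a log2 fold change of 0.60 ± 0.34 and was not called (adjusted p = 0.179). Scaling by library size only turned the balance of calls, with 45.5% higher against 56.1% with TMM scaling.

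The second comparison asked the same of 129S6/SvEvTac aortas. Of 20 collagens 17 rose here too, and of 22 crosslinking genes 18, while the contractile genes had a median log2 fold change of -0.02. Col1a1 rose from 1845 ± 556 to 6745 ± 2187 CPM (SD, n = 4), a log2 fold change of 1.87 ± 0.25 (SE, adjusted p = 0.000266), and Eln rose 4.46-fold. Acta2 had a log2 fold change of 0.06 ± 0.18 (adjusted p = 0.872) and Myh11 one of -0.25 ± 0.26 (adjusted p = 0.603). By edgeR's test 1321 genes rose and 766 fell, 2087 in all.

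Collagens had 17 of 20 genes higher (17 adjusted over the list alone, median 1.23, camera adjusted p = 1.19e-37), with Col5a2 up 4.25-fold. Crosslinking genes had 18 of 22 higher (19 adjusted over the list alone, camera adjusted p = 2.11e-27), with Lox up 4.05-fold and Plod2 up 2.37-fold. Matricellular proteins and proteoglycans had 14 of 27 higher and 1 lower (17 and 1 adjusted over the list alone, camera adjusted p = 9.03e-19), with Fn1, fibronectin, up 3.28-fold and Postn up 3.55-fold. Elastic fibre genes had 9 of 17 higher (11 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.84e-09), with Fbln5, fibulin 5, up 1.99-fold. Matrix proteases and their inhibitors had 11 of 28 higher and 1 lower (15 and 1 adjusted over the list alone, camera adjusted p = 3.39e-08), with Adam12 up 9.56-fold. All 5 also passed with an estimated correlation, at an adjusted p of 0.005 for the first 3 and 0.018 for the last 2. Among single genes Gkn3 fell 6.36-fold and Ccl11, eotaxin, fell 3.55-fold.

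Cell cycle genes had 22 of 28 higher in 129S6/SvEvTac (25 adjusted over the list alone, median 2.52, camera adjusted p = 1.38e-28; adjusted p = 0.0601 with an estimated correlation), with Ccnb1, cyclin B1, up 18.6-fold. Endoplasmic reticulum stress genes had 12 of 23 higher (15 adjusted over the list alone, camera adjusted p = 2.41e-07; adjusted p = 0.189 with an estimated correlation). Integrins, focal adhesion and mechanosensing genes had 7 of 25 higher (12 adjusted over the list alone, camera adjusted p = 2.71e-06; adjusted p = 0.133 with an estimated correlation). Itga5, the fibronectin receptor chain, rose 3.68-fold and Piezo1, a stretch-gated channel with an antisense overlap that leaves its count uncertain, rose 2.02-fold. Osteochondrogenic genes had 5 of 16 higher (6 adjusted over the list alone, camera adjusted p = 0.00765; adjusted p = 0.133 with an estimated correlation). Endothelial markers had 5 of 26 higher (8 adjusted over the list alone, camera adjusted p = 0.00327; adjusted p = 0.746 with an estimated correlation), a call lost without 129S6/SvEvTac AngII replicate 2 (0.152). Monocyte and macrophage markers had 1 of 28 higher (1 adjusted over the list alone, camera adjusted p = 0.0382; adjusted p = 0.746 with an estimated correlation), a call lost without 129S6/SvEvTac AngII replicate 1 (0.142) or 5 (0.13) or control replicate 4 (0.269), and with the adipocyte score as a covariate (0.205). Adipocyte markers had 1 of 26 higher (1 adjusted over the list alone, camera adjusted p = 0.0426; adjusted p = 0.785 with an estimated correlation), lost without AngII replicate 5 (0.206) or control replicate 3 (0.227). The contractile list had 0 of 26 genes called by edgeR's test (0 adjusted over the list alone, median -0.02, camera adjusted p = 0.828). The interferon, chemokine and antigen presentation lists were not called, with camera adjusted p of 0.828, 0.212 and 0.286. In the smooth muscle contractile, interferon and skeletal muscle lists the median and the test pointed down while the mean was above 0. Scaling by library size only moved the median log2 fold change of all genes from 0.00272 to -0.157 and left 25.2% of calls higher, against 63.3% with TMM scaling.

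**Figure D2:**
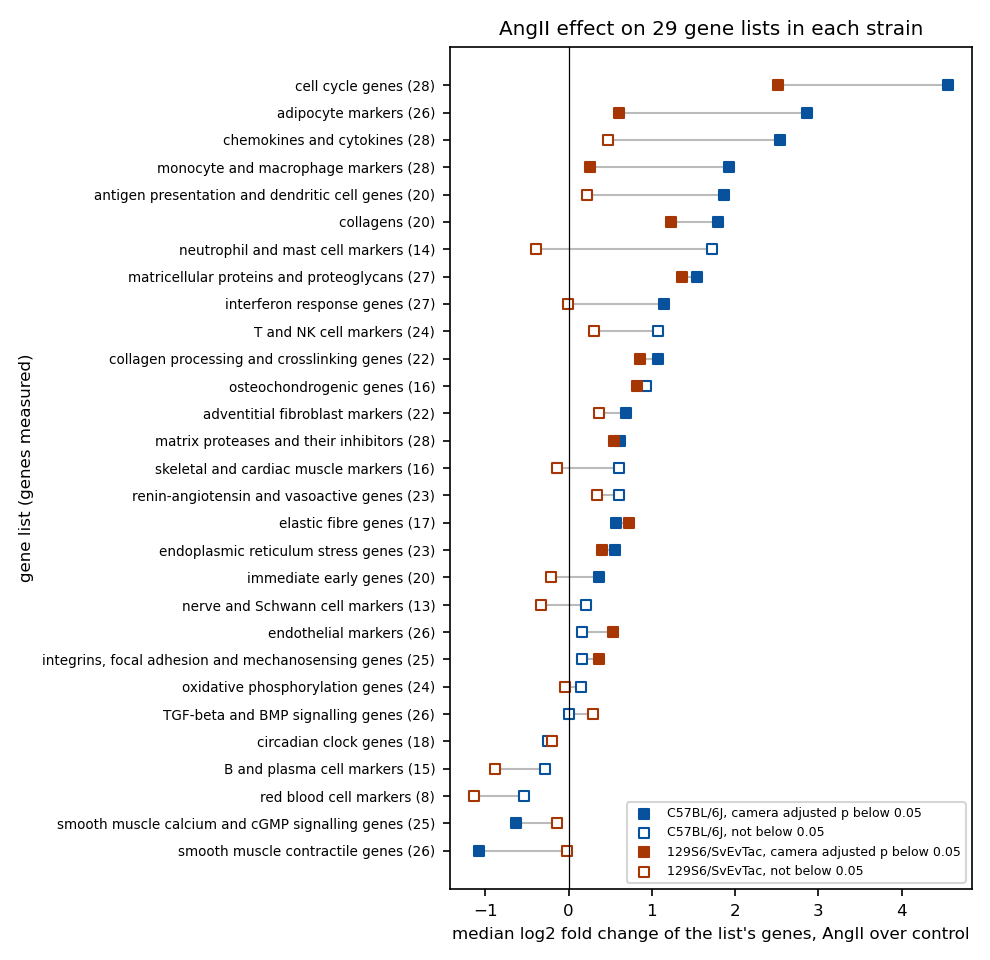
Median log2 fold change of each of 29 gene lists for AngII over control in C57BL/6J (blue) and 129S6/SvEvTac (brown), with the number of genes measured; filled squares passed camera at an adjusted p below 0.05. The contractile list lies at -1.07 in C57BL/6J and -0.02 in 129S6/SvEvTac, and the collagen list at 1.80 and 1.23.

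The effects overlapped. Of the called genes, 917 rose in both strains against 288.3 expected of independent lists, and 563 fell in both against 130.9 expected; no library was shared between these comparisons. Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.48 and a Spearman rho of 0.509. Of the 1480 genes called in both strains in the same direction, 1050 had the larger estimate in C57BL/6J, with a median ratio of log2 fold changes of 1.30, but only 198 passed the test of the difference, 180 of them larger in C57BL/6J and 18 larger in 129S6/SvEvTac. Another 48 genes were called in opposite directions, and all 48 also passed the test of the difference. A difference of opposite effects is larger than either effect, so that pass adds little.

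**Figure D3:**
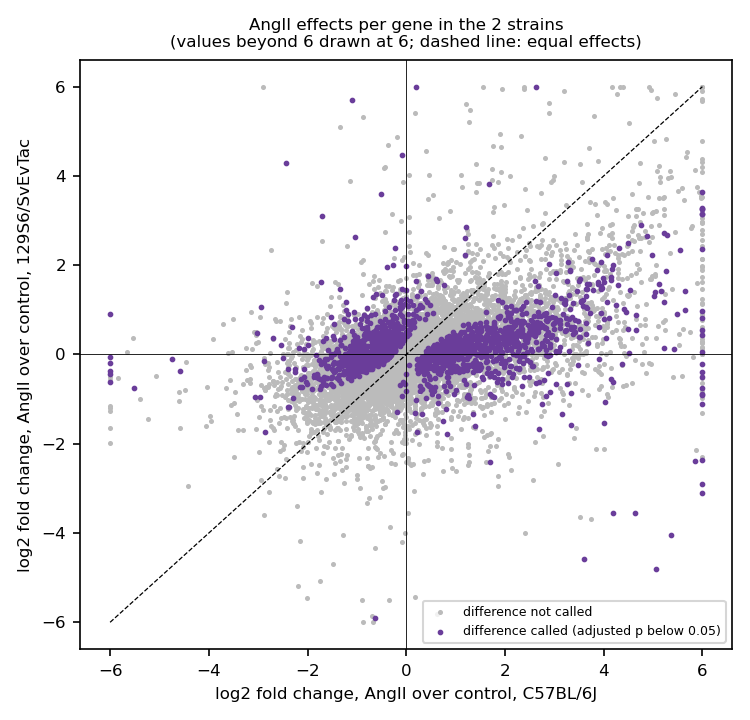
Log2 fold change of each of 17125 genes for AngII over control in C57BL/6J (horizontal) and 129S6/SvEvTac (vertical), with values beyond 6 drawn at 6 and a dashed line where the effects are equal. Purple points are the 1706 genes whose effects differed between strains at an adjusted p below 0.05.

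The third comparison asked where the AngII effect itself differed, as the C57BL/6J effect minus the 129S6/SvEvTac effect. The effect was lower in C57BL/6J for 19 of 26 contractile genes, and higher for 10 of 28 chemokines and cytokines and 16 of 28 macrophage markers, though no list passed with an estimated correlation (adjusted p of 0.154, 0.105 and 0.263 for these). The same lists passed with fry (adjusted p of 0.00251, 0.000733 and 0.0134 in that order). Acta2 had a difference of -1.01 ± 0.25 (SE, n = 4 per group, adjusted p = 0.0207) and Lmod1 one of -1.49 ± 0.23 (adjusted p = 0.00192). Ccl2 had a difference of 3.92 ± 0.82 (adjusted p = 0.00951) and Cxcl12, a chemokine of stromal cells, had an effect 2.84-fold higher (adjusted p = 0.000795). By edgeR's test 914 differences were above 0 and 792 below, 1706 in all. Of these genes 1283 were called for AngII in C57BL/6J alone, 137 in 129S6/SvEvTac alone, 246 in both and 40 in neither.

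Of the contractile genes 19 of 26 had a difference below 0 (23 adjusted over the list alone, median -1.05, camera adjusted p = 3.81e-20; adjusted p = 0.154 with an estimated correlation), among them Des, desmin, at -1.29 ± 0.20. Myh11 had a difference of -1.35 ± 0.36 (adjusted p = 0.0303). Its call was lost without any 1 of these libraries: C57BL/6J AngII replicate 2 (0.0531) or 5 (0.0555), C57BL/6J control 1 (0.054) or 3 (0.0561), 129S6/SvEvTac AngII 2 (0.0538) or 4 (0.0616), and 129S6/SvEvTac control 1 (0.0576), 2 (0.0609) or 3 (0.0519). Smooth muscle calcium and cGMP genes had 2 of 25 below 0 and 1 above (4 and 2 adjusted over the list alone, camera adjusted p = 0.00221; adjusted p = 0.485 with an estimated correlation), the latter being Ednra at 1.95 ± 0.34. With the adipocyte score as a covariate the call of that list was lost (adjusted p = 0.0505). Integrins, focal adhesion and mechanosensing genes had 8 of 25 below 0 and 1 above (12 and 2 adjusted over the list alone, camera adjusted p = 0.000267; adjusted p = 0.395 with an estimated correlation), with Itga9 at -1.02 ± 0.17.

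Chemokines and cytokines had 10 of 28 differences above 0 (15 adjusted over the list alone, camera adjusted p = 4.17e-11; adjusted p = 0.105 with an estimated correlation), including Ccl7 at 4.11 ± 0.72. Monocyte and macrophage markers had 16 of 28 above 0 (21 above and 1 below adjusted over the list alone, camera adjusted p = 4.94e-14; adjusted p = 0.263 with an estimated correlation), including Adgre1 at 2.02 ± 0.36 and Mrc1, the macrophage mannose receptor, at 1.62 ± 0.31. Cd68 had a difference of 1.89 ± 0.47 (adjusted p = 0.0219), a call lost without 129S6/SvEvTac control replicate 2 (adjusted p = 0.0508) and with the adipocyte score as a covariate (0.0634). Interferon response genes had 4 of 27 above 0 (14 adjusted over the list alone, camera adjusted p = 3.62e-06; adjusted p = 0.437 with an estimated correlation). Cell cycle genes had 11 of 28 above 0 and 2 below (21 and 2 adjusted over the list alone, camera adjusted p = 1.12e-08; adjusted p = 0.436 with an estimated correlation). Antigen presentation and dendritic cell genes had 0 of 20 called by edgeR's test (7 above 0 adjusted over the list alone, camera adjusted p = 0.000214; adjusted p = 0.442 with an estimated correlation). Neutrophil and mast cell markers had 4 of 14 above 0 (6 adjusted over the list alone, camera adjusted p = 0.00481; adjusted p = 0.436 with an estimated correlation). Immediate early genes had 4 of 20 above 0 (5 adjusted over the list alone, camera adjusted p = 0.000115; adjusted p = 0.436 with an estimated correlation), including Socs3 at 2.50 ± 0.31. The adipocyte list moved in the same direction, with 1 of 26 genes called (0 adjusted over the list alone, median 2.25, camera adjusted p = 0.000573; adjusted p = 0.688 with an estimated correlation), and its call was lost without C57BL/6J AngII replicate 1 (0.0524).

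Matrix proteases had 10 of 28 differences above 0 and 1 below (10 and 3 adjusted over the list alone, camera adjusted p = 4.33e-06; adjusted p = 0.105 with an estimated correlation), with Mmp14 at 1.54 ± 0.19. Collagens had 5 of 20 above 0 and 1 below (12 and 2 adjusted over the list alone, camera adjusted p = 0.000137; adjusted p = 0.436 with an estimated correlation). Col8a1 had a difference of 2.60 ± 0.51 and Col18a1, the source of endostatin, one of -0.78 ± 0.15. Col1a1 and Col3a1 had differences of 1.11 ± 0.34 and 0.95 ± 0.29 that missed the threshold, with adjusted p of 0.0518 and 0.0508. Col1a1 passed without C57BL/6J AngII replicate 3 (0.0151), 129S6/SvEvTac AngII replicate 1 (0.0213) or 129S6/SvEvTac control replicate 3 (0.0398), and Col3a1 without the same libraries (0.0234, 0.0199 and 0.0371). Matricellular proteins had 6 of 27 above 0 and 2 below (12 and 3 adjusted over the list alone, camera adjusted p = 0.00406; adjusted p = 0.395 with an estimated correlation). Adventitial fibroblast markers had 5 of 22 above 0 (6 adjusted over the list alone, camera adjusted p = 0.0212; adjusted p = 0.688 with an estimated correlation), a call lost without C57BL/6J AngII 5 (0.175), 129S6/SvEvTac AngII 2 (0.0868) or 129S6/SvEvTac control 2 (0.0698), and with the adipocyte score as a covariate (0.0992). Eln had a difference of -0.36 ± 0.39 (adjusted p = 0.62). Single genes outside the called lists included Smad6 at -2.13 ± 0.21, Id2, an inhibitor of DNA-binding factors, at -2.05 ± 0.29, and Ptgis, prostacyclin synthase, at -1.03 ± 0.14. Pcdhgc3, a protocadherin, had a difference of -4.81 ± 1.02, but it shares exons with its neighbours, its count is uncertain, and the call was lost with limma (adjusted p = 0.146). In 4 lists the median was above 0 while the test pointed down or the mean lay below 0: renin-angiotensin, skeletal muscle, osteochondrogenic and circadian clock genes. The endothelial list had a median of -0.30 and a mean of 0.06. The count of 1706 was sensitive to single libraries, at 1039 without 129S6/SvEvTac control replicate 2, 1076 without 129S6/SvEvTac AngII replicate 4 and 2990 without C57BL/6J AngII replicate 3. The balance of directions depended on the processing: 53.6% of differences were above 0 with TMM scaling, 65.2% with library size only, 47.9% with protein-coding genes only, 47.5% without C57BL/6J control replicate 2 and 49.7% without C57BL/6J control replicate 5.

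**Figure D4:**
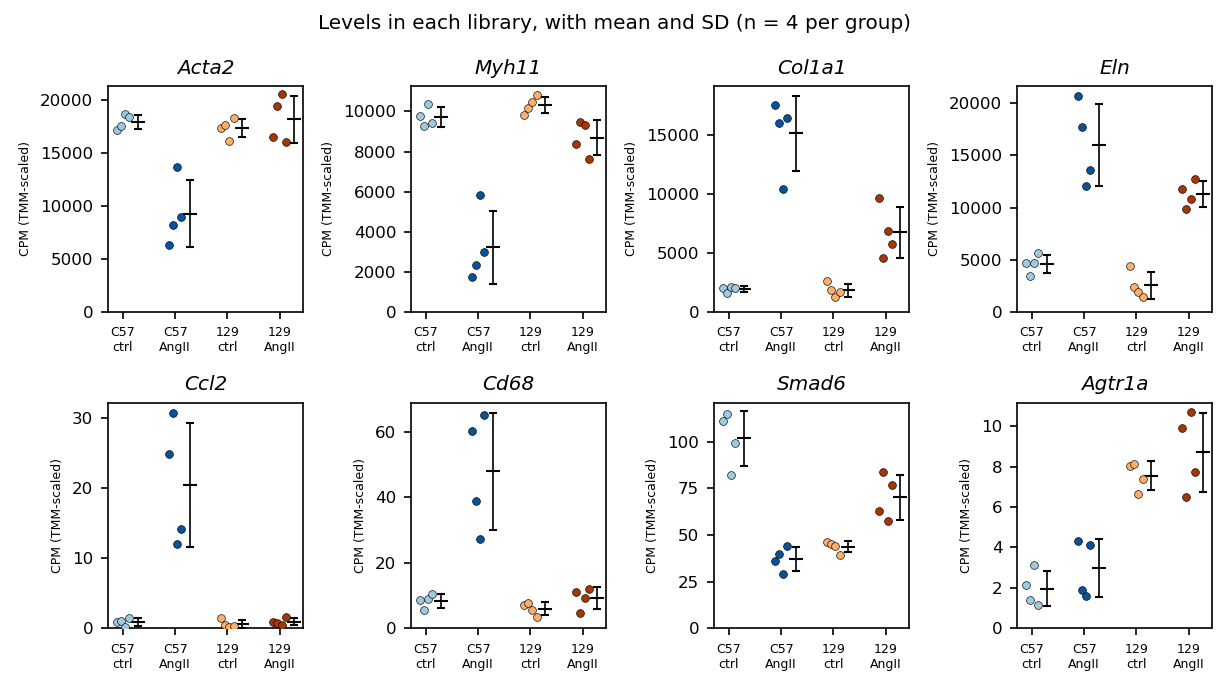
CPM of 8 genes in each library (points), with mean and SD beside them, in the 4 groups of 4 libraries. Acta2 averaged 9294 CPM in C57BL/6J AngII and 18186 CPM in 129S6/SvEvTac AngII, and Agtr1a 1.96 CPM in C57BL/6J control and 7.55 CPM in 129S6/SvEvTac control.

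The fourth comparison was between the strains without AngII, as C57BL/6J minus 129S6/SvEvTac. Agtr1a was lower in C57BL/6J, at 1.96 ± 0.877 CPM against 7.55 ± 0.706 CPM (SD, n = 4), a log2 fold change of -1.94 ± 0.35 (SE, adjusted p = 0.00148). Acan, aggrecan, was 9.28-fold higher in C57BL/6J and Sox9, a chondrocyte factor, 5.81-fold higher. Acta2, Myh11 and Col1a1 were not called, with log2 fold changes of 0.05, -0.09 and 0.06 and adjusted p of 0.924, 0.896 and 0.925. By edgeR's test 916 genes were higher in C57BL/6J and 867 lower, 1783 in all. The share that was higher, 51.4%, fell to 49.3% with library size only and to 48% with the adipocyte score as a covariate. The balance also turned with the replicate block, with only the groups compared and without some single libraries, while RLE scaling and DESeq2 kept it.

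Several of the largest differences were in genes with near-identical copies, so their counts are uncertain. Trim12a had no counts in 129S6/SvEvTac controls and was at least 922-fold higher in C57BL/6J, against a floor of 3 counts over the group. The ribosomal protein copies Rps3a2 and Rps3a3 were 260-fold and 181-fold lower in C57BL/6J, and Eno1b, an enolase copy, 254-fold lower. Among other genes Slc6a17, a neutral amino acid transporter, was 48.3-fold higher in C57BL/6J. Hal, histidine ammonia lyase, was 196-fold lower. Osteochondrogenic genes had 4 of 16 higher (5 adjusted over the list alone, camera adjusted p = 0.0305; adjusted p = 0.947 with an estimated correlation), a call lost without C57BL/6J control replicate 3 (0.0767). Monocyte and macrophage markers had 4 of 28 higher and 1 lower (4 and 1 adjusted over the list alone, camera adjusted p = 0.0305; adjusted p = 0.947 with an estimated correlation), with Fcer1g, an Fc receptor chain, up 2.34-fold; the call was lost without C57BL/6J control replicate 3 (0.0572) or 129S6/SvEvTac control replicate 4 (0.138). Cell cycle genes had 3 of 28 higher (3 adjusted over the list alone, camera adjusted p = 0.0305; adjusted p = 0.947 with an estimated correlation), including Mcm6, a helicase subunit, 24.5-fold. The other 26 lists were not called. In the matricellular and smooth muscle calcium lists the median lay below 0 while the test pointed up, and in the renin-angiotensin and neutrophil lists it lay above 0 while the test pointed down.

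The fifth comparison was between the strains with AngII. Most contractile genes were lower, and most monocyte and macrophage markers and chemokines and many collagens higher, in C57BL/6J. Acta2 had a log2 fold change of -0.97 ± 0.18 (SE, n = 4 per group, adjusted p = 0.000757), Ccl2 one of 4.42 ± 0.61 (adjusted p = 7.35e-05) and Col1a1 one of 1.17 ± 0.24 (adjusted p = 0.0019). Agtr1a stayed lower in C57BL/6J, at -1.54 ± 0.34 (adjusted p = 0.0029). By edgeR's test 2875 genes were higher and 2492 lower, 5367 in all; the share that was higher was 53.6% with TMM scaling, 61.8% with library size only and 49.6% with protein-coding genes only, where the balance turned.

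The contractile list had 24 of 26 genes lower (24 adjusted over the list alone, median -0.98, camera adjusted p = 5.98e-14; adjusted p = 0.275 with an estimated correlation), with Des 3.99-fold lower and Csrp1, a cytoskeletal regulator of muscle, 2.68-fold lower. Monocyte and macrophage markers had 23 of 28 higher (24 higher and 1 lower adjusted over the list alone, camera adjusted p = 6.86e-15; adjusted p = 0.275 with an estimated correlation), with Cd68 5.17-fold and Fcgr1, an Fc receptor, 10.2-fold. Chemokines and cytokines had 21 of 28 higher (22 adjusted over the list alone, camera adjusted p = 2.24e-10; adjusted p = 0.0551 with an estimated correlation). Matrix proteases had 17 of 28 higher and 1 lower (17 and 1 adjusted over the list alone, camera adjusted p = 1.09e-07; adjusted p = 0.0551 with an estimated correlation). Collagens had 12 of 20 higher and 1 lower (15 and 1 adjusted over the list alone, camera adjusted p = 0.000243; adjusted p = 0.443 with an estimated correlation). Elastic fibre genes had 7 of 17 higher and 5 lower (8 and 5 adjusted over the list alone) and were not called (camera adjusted p = 0.71). All 28 cell cycle genes were higher (28 adjusted over the list alone, camera adjusted p = 4.3e-13; adjusted p = 0.277 with an estimated correlation). Antigen presentation and dendritic cell genes had 18 of 20 higher (18 adjusted over the list alone, camera adjusted p = 2.69e-07, adjusted p = 0.277 with an estimated correlation). Cd209a, a dendritic cell lectin, was at least 744-fold higher against the floor of 3 counts over the group. Cd209a also had no counts in 129S6/SvEvTac controls and was at least 35.7-fold higher in C57BL/6J controls, so its strain difference was present without AngII. Interferon response genes had 21 of 27 higher and 1 lower (22 and 1 adjusted over the list alone, camera adjusted p = 1.57e-05; adjusted p = 0.443 with an estimated correlation). Immediate early genes had 15 of 20 higher (16 adjusted over the list alone, camera adjusted p = 6.45e-07; adjusted p = 0.277 with an estimated correlation). Camera also called crosslinking (0.00513; adjusted p = 0.443 with an estimated correlation), matricellular (0.00707; 0.277) and adventitial fibroblast (0.00424; 0.54) genes upward and smooth muscle calcium genes (0.0199; 0.583) downward. Endoplasmic reticulum stress genes were called upward (0.0162; adjusted p = 0.568 with an estimated correlation) but not without C57BL/6J AngII replicate 2 (0.0681). Osteochondrogenic genes were called upward (0.0337; adjusted p = 0.277 with an estimated correlation) but not without C57BL/6J AngII replicate 3 (0.0546) or 129S6/SvEvTac AngII replicate 5 (0.0585). Integrins and focal adhesion genes were called downward (0.0412; adjusted p = 0.54 with an estimated correlation) but not without C57BL/6J AngII replicate 1 (0.0826) or 5 (0.0875) or 129S6/SvEvTac AngII replicate 2 (0.0631). Neutrophil and mast cell markers were called upward (0.0415; adjusted p = 0.443 with an estimated correlation) but not without C57BL/6J AngII replicate 1 (0.0833), 2 (0.059) or 5 (0.0875), 129S6/SvEvTac AngII replicate 1 (0.0602), 4 (0.0782) or 5 (0.0554), or 129S6/SvEvTac control replicate 1 (0.0555) or 2 (0.051). The adipocyte list, with 2 of 26 higher and 1 lower (0 and 1 adjusted over the list alone), was not called here (camera adjusted p = 0.492). In the renin-angiotensin list the median lay above 0 while the test pointed down, and in the T and NK cell and B and plasma cell lists it lay below 0 while the test pointed up.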

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

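Chosen only after the results were seen were Cochran's Q on the contractile genes, with and without Casq2, both tests of pseudogenes and the test of switching genes.

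A sample stood far from the other 3 of its group in 22 of 316 groups of named genes and library measures examined, against 15.8 expected by chance, about 1 group in 20. That expectation assumes independent, normally spread values, while most values were CPM and the genes share libraries. Where the others held 0 CPM, any count passed, so 15.8 is a rough guide only. In 129S6/SvEvTac control replicate 3 the values were Acan 7.28 CPM (others 3.91 to 4.3), Casq2 7.45 CPM (others at most 2.01), Eno1b 34.4 CPM (others 40.8 to 41.8) and Pcdhgc3 14 CPM (others 12.6 to 12.8). In 129S6/SvEvTac control replicate 2 the values were Adam12 3.12 CPM (others 1.1 to 1.24), Il6 0.0564 CPM (others 0) and Nnt 13 CPM (others 1.95 to 2.17). In C57BL/6J AngII replicate 1 the value was Casq2 7.96 CPM (others 0.411 to 1.65). In 129S6/SvEvTac control replicate 1 the values were Ccl2 1.47 CPM (others 0.253 to 0.451), Lox 248 CPM (others 142 to 156) and Tnn 0.113 CPM (others 0). In C57BL/6J control replicate 2 the values were Col18a1 2170 CPM (others 2670 to 2740), Col1a1 1570 CPM (others 2010 to 2090) and Col3a1 2290 CPM (others 2820 to 2890). In 129S6/SvEvTac AngII replicate 1 the value was Des 201 CPM (others 268 to 278). In C57BL/6J control replicate 5 the values were Gucy1a1 261 CPM (others 309 to 318) and Pcdhgc3 120 CPM (others 12.4 to 22.6). In C57BL/6J AngII replicate 2 the value was Hal 0.065 CPM (others 0). In 129S6/SvEvTac AngII replicate 5 the value was Il6 0.0524 CPM (others 0). In 129S6/SvEvTac AngII replicate 4 the value was Ppp1r14a 262 CPM (others 222 to 225). The total count of 129S6/SvEvTac AngII replicate 5 was 121573945 (others 44029105 to 48900644), and the adipocyte score of C57BL/6J control replicate 1 was 4.25 mean log2 CPM (others 2.81 to 2.98).

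Of all 17125 genes tested, 1706 (9.96%) had an AngII effect that differed between the strains. The naming rule drew partly on this difference, so the share among named genes is raised by that choice. The AngII effect differed between the strains for 38 of 68 genes named, as C57BL/6J minus 129S6/SvEvTac in log2. Above 0 were Adam12 3.92, Adgre1 2.02, Ccl2 3.92, Ccl7 4.11, Cd14 1.85, Cd68 1.89, Cenpe 2.51, Col8a1 2.60, Cxcl12 1.5, Ednra 1.95, Fcer1g 1.84, Fcgr1 2.09, Il6 11.72, Lox 0.88, Lum 1.60, Mmp14 1.54, Mrc1 1.62, Myc 2.37, Socs3 2.50, Spp1 5.61 and Timp1 2.27. Below 0 were Acta2 -1.01, Adra1d -1.93, Col18a1 -0.78, Csrp1 -1.27, Des -1.29, Fbln5 -0.79, Id2 -2.05, Itga9 -1.02, Lmod1 -1.49, Mcm6 -1.31, Myh11 -1.35, Npr1 -1.02, Pcdhgc3 -4.81, Ppp1r14a -1.54, Ptgis -1.03, Slc6a17 -2.36 and Smad6 -2.13. The Il6 value is a fitted one against near-empty groups, depends on the prior count, and its call was lost without 129S6/SvEvTac control replicate 2 (adjusted p = 1). The call of Spp1 was lost with limma (adjusted p = 0.0574). That of Lox was lost with the adipocyte score as a covariate (0.0974), with replicate number as a block (0.0512), with 2 libraries left out (0.0554), and without any 1 of C57BL/6J AngII replicates 1 (0.0632) and 2 (0.0628), C57BL/6J control replicates 1 (0.0522), 2 (0.089), 3 (0.0604) and 5 (0.06), 129S6/SvEvTac AngII replicates 1 (0.0594), 2 (0.0694) and 4 (0.0728), and 129S6/SvEvTac control replicates 1 (0.0586) and 2 (0.0503).

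Of 26 contractile genes 23 were lower and 1 higher in C57BL/6J AngII aortas, with a median log2 fold change of -1.07 and a list call lost with an estimated correlation (adjusted p = 0.132), and 3 technical causes were tested. With the adipocyte score as a covariate the median was -0.763, or -0.98 to -0.546 within 1 standard error of a median over the 26 genes. That error came from the fit without the covariate and treats the genes as independent, so it overstates the certainty. The fall was smaller but remained, so perivascular fat as this score measures it is unlikely to be the whole cause. Leaving out 1 library gave at most -0.905. A smaller share of smooth muscle RNA that lowers all its genes alike is unlikely to be the whole cause, because the members differ beyond their errors (Cochran's Q, n = 26 genes with edgeR standard errors, p = 2.97e-32, values from -1.67 for Synpo2 to 2.96 for Casq2; without Casq2, n = 25 genes, p = 2.42e-30). The genes share libraries, so that test overstates its certainty. A loss of muscle cells together with a change within them was not tested.

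Pseudogenes made up 194 of 1783 calls between control strains (10.9%) and 87 of 6664 calls for AngII in C57BL/6J (1.31%), an odds ratio of 9.23 (7.08 to 12.1). They were 739 of all genes tested (4.32%) and 227 of 5367 calls between AngII strains (4.23%), of which 195 were higher in 129S6/SvEvTac; the larger number of other calls lowers that share. Of the 194, 175 were higher in 129S6/SvEvTac. Between AngII strains 92.3% of the 194 (87.6 to 95.6) were called in the same direction, but as they were picked by a difference without AngII this tests no cause. Reads of 129S6/SvEvTac placed on other copies by their match to a C57BL/6J reference and real differences in pseudogene expression would both give the odds ratio, so they cannot be told apart here.

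In 90 genes, Nnt and Pcdhgc3 among them, the sorted libraries of a group had a gap of at least 3 in log2 CPM. The highest library of that group reached at least 8 CPM. Of the 90, 7 were adipocyte, skeletal and cardiac muscle or red blood cell markers, and others were liver genes such as Alb. Exon overlap with another measured gene was found for 37.8% of the 90 and 22.8% of others. That odds ratio of 2.05 (1.3 to 3.21) leaves open whether reads assigned between genes could be the cause. Of 34 with such partners, 23 correlated negatively with them within groups (median correlation -0.344). Adding the partners' counts took the median SD from 2.15 to 0.305 in log2, a fall that partners with higher counts would also give.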

How the results depend on the processing

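The alternatives that left out 2 libraries, switching genes, Gm42418 or all but protein-coding genes were chosen only after the results were seen.

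Leaving out 1 library gave 5740 to 7173 genes for AngII in C57BL/6J, 1402 to 2634 in 129S6/SvEvTac, 1354 to 2118 between control strains, 4478 to 6088 between AngII strains and 1042 to 1838 shared by the AngII effects. For the difference of effects it gave 1039 (without 129S6/SvEvTac control 2) to 2990 (without C57BL/6J AngII 3), with 1076 without 129S6/SvEvTac AngII 4. The difference of effects also moved to 1118 with the adipocyte covariate, 2670 with limma, 2642 with DESeq2 and 1049 with 2 libraries of high fat or muscle signal left out. With limma the 129S6/SvEvTac effect had 3324 genes and the control strains 3209. With only the groups compared the control strains had 2772, the AngII strains 3666, AngII in C57BL/6J 5554 and AngII in 129S6/SvEvTac 2752. At an adjusted p below 0.01 the overlap was 616, by the stricter threshold itself. Without C57BL/6J AngII 3, the library with the lowest limma weight (0.256), the count rose in every comparison. That includes AngII in 129S6/SvEvTac (2634) and the control strains (2118), which do not hold that library. All comparisons share 1 estimate of each gene's spread over the 16 libraries. Apart from the stricter threshold, the cause was not tested.

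Of the results for named genes with 1 library left out, 6346 stayed the same, 447 lost the call and 7 gained it. For lists the counts were 2226, 29 and 65. These counts include libraries left out that were not in the comparison, and results not called either way count as the same. Both raise the number that stayed the same. With an estimated correlation 54 list calls were lost, and those that held were 4 in C57BL/6J and 5 in 129S6/SvEvTac, with none between strains or for the difference of effects. With fry 12 list calls were lost and 6 were gained. With the adipocyte covariate, Cox5a in C57BL/6J turned from a call upward to -0.0658 (adjusted p = 0.813) and the oxidative phosphorylation genes in C57BL/6J, not called without it, to a call downward with a median of -0.342 (adjusted p = 0.00215); the cause was not tested. A marker list was not tested against its own covariate.

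With the replicate number as a block the counts were 6175, 1426, 1590, 1383 and 4459 in the order of the comparisons. Correlations of pairs sharing a number ran from -0.06 to 0.146. These few values were not compared with unmatched pairs, so they do not settle whether numbers pair the samples. What depth alone limits was not tested. In simulated data at these depths, 22.4% of genes changed 1.5-fold in the C57BL/6J AngII group were recovered. That simulation had 4 samples per group and 1 spread per gene for all groups. Only 200 genes were changed in it, against 6664 called in the real data, so the adjustment of p was stricter. The share therefore does not measure recovery in the real comparison.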

Other observations

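The idea of liver RNA came only after Alb, Apoa1, Ttr and Fabp1 were seen highest in 1 library, although its test was written before being run; the group splits were planned.

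Reshuffling the group labels gave at least as many genes as the real grouping in 1 of 35 splits for each comparison within 8 libraries, the real one. The real and highest other counts were 6664 and 4 (AngII in C57BL/6J), 2087 and 2 (AngII in 129S6/SvEvTac), 1783 and 1 (control strains) and 5367 and 390 (AngII strains). For the difference of effects it was 1 of 100, with 1706 and 16. There the control and AngII labels were reshuffled within each strain, which removes the AngII effect of both strains. That count therefore does not test whether the effects of the 2 strains are equal.

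Of 20 other liver genes, 16 had their highest CPM in 129S6/SvEvTac control replicate 3, 80% (56.3 to 94.3). The value lies exactly on the bound set for liver RNA in that library, and the interval reaches well below that bound. The whole interval lies above the separate, lower bound that was set against liver RNA.

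The adipocyte score averaged 5.453 ± 1.67 in C57BL/6J AngII and 3.222 ± 0.691 in C57BL/6J controls (mean log2 CPM, SD, n = 4, exact permutation p = 0.0571, adjusted p = 0.314). The endothelial score averaged 5.495 ± 0.135 and 4.946 ± 0.0493 in the same groups (exact permutation p = 0.0286, adjusted p = 0.252). The mitochondrial share of counts was 2.614 ± 0.808% and 2.662 ± 0.264% (exact permutation p = 0.886). The adjustment ran over 44 such tests, and 0.0286 is the smallest p each can give. A few tests at that p could not pass, so the adjusted values are no evidence that the groups were alike.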
